A study of Arabidopsis thaliana with 6 samples.

How the data were processed

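Total RNA from roots of 7-day-old Arabidopsis thaliana seedlings was measured on 6 single-colour (Cy3) Agilent arrays, 3 for the wild type Col-0 and 3 for lecrk-I.9-1, a T-DNA insertion line in the lectin receptor kinase gene LecRK-I.9 that the submitters describe as a loss of function. Per the labels' protocols, seedlings grew in liquid half-strength Murashige and Skoog medium, each flask was a separate plant population giving 1 replicate, and root segments from between the root tip meristem and the hypocotyl were pooled per flask. Genotype and replicate number were taken from the sample titles, which the genotype labels match. The source names of the 3 lecrk-I.9-1 samples read as wild type with replicate numbers continuing from the wild-type series, so 1 label field of these samples conflicts with the others.

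The deposited scanner files hold spot intensity values, made with Agilent Feature Extraction, for a design whose probes were placed on the TAIR10 genome build, per the file headers. The authors' processed signal in these files is a background-subtracted intensity on a linear scale, not yet normalised between arrays. The deposited value table of the series holds 1 intensity per transcript on a linear scale. Its 6 columns hold the same set of sorted values, with a median of 184.3 in each, as quantile normalisation gives. The method and centring behind it are not given in the sources used here. Each column followed the scanner values of its own array (r of gene-centred values between 0.885 and 0.919 across transcripts, against at most 0.224 with any other array), which settled its scale and direction.

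Each array carried 62976 spots, of which 1319 were controls and were left out. No non-control spot was saturated on any array, and between 22 and 30 spots per array had an outlier flag and were left out. The processed signal was taken to log2 and shifted by each array's 75th percentile over non-control spots, so that every value below is a log2 signal relative to that percentile. Spots of 1 probe were averaged. A probe was tested where it was well above background on all 3 arrays of at least 1 genotype, and a gene with several tested probes was represented by the one with the highest mean over the 6 arrays. This left 22468 genes out of 30541 loci on the array. Among 15402 loci with several tested probes, the probes of 3221 differed in the sign of the genotype difference, and the median correlation of 2 probes of a gene across the arrays was 0.893. Gene names came from the files, or from a table of NCBI gene names (assembly TAIR10.1) in which 29870 of the loci were found; coordinates are those of the files.

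Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 32 lists, and again with the correlation between genes estimated from the data. The estimated correlation had a median of 0.306 over the lists and reached 0.983 (photosynthesis), so a camera p at the preset can be far too small. A list member was also counted "adjusted over the list alone". The number of arrays limits the precision: the median standard error of a log2 difference was 0.189. On data simulated from the means and spreads of the 22468 genes of this comparison, the fit recovered 34% of 50 genes changed 2-fold, 78% at 4-fold, 96% at 8-fold and 98% at 16-fold. In that simulation, 13 unchanged genes were called, the shifted list was called, and 0 of the 31 other lists were. The simulation drew genes independently, without the array structure of the real data. It also held many changed genes at once, which makes the adjusted threshold easier to pass. Its shares are therefore not those to expect here, where an 11.3-fold difference (AT5G35935) had a limma adjusted p of 0.366.

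The comparison, the tests, the 32 gene lists and the rule for the genes named were set before the data were examined. The lists cover lectin receptor kinases of clade I, hormone and defence responses, cell wall and root tissues, nutrient responses, and markers of shoot tissue, root tip, root cap and harvest time. Some genes stand in several lists. ACO1 and ETR2 are in the ethylene and core hypoxia lists, and ACS6 is in the ethylene and rapid elicitor lists. CYP81F2 and MYB51 are in the rapid elicitor and camalexin lists. Calls of these lists are therefore not fully separate. The rule names LecRK-I.9, then either the genes of largest change among those past the threshold or, where fewer than 10 pass, the 10 genes of smallest p as values. It adds up to 4 members of each list that pass or, where none passes, at most the 2 of smallest p as values, and genes past the threshold near the insertion. No list member had a symbol that the name table gives to another locus, so none was left out; 57 of the 600 members are called by another symbol or by locus code where the table does not give the listed symbol. Genes named outside this rule are marked as chosen after their values were seen.

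The file headers place the arrays in 3 scans, which coincide with the slides where a slide is given. Scan 1 held wild type replicate 1 and lecrk-I.9-1 replicates 2 and 3, scan 2 held wild type replicate 2 and lecrk-I.9-1 replicate 1, and wild type replicate 3 was scanned alone. Values within scans 1 and 2 and with scan as a block are given beside LecRK-I.9 and the lists called; for other lists, the block's median is given where its sign turns. The other settings tried were quantile normalisation, normexp background correction with an offset of 50, the authors' value table, no filter and a stricter filter on dim probes, the mean over probes, an intensity trend with robust estimation, the replicate number as a block, array weights, and leaving out each array in turn; arrays left out did not alter the set of genes tested. Fry set tests, and leaving out wild type replicates 1 and 3 together, were added after the data were seen. Where a probe was well above background on 0 of the 3 arrays of 1 genotype, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. Such a bound compares means and leaves out the spread between arrays. It rests on the lowest signal of any probe on the array, not on the limit of the probe itself. A fold given as "at least" is therefore not a strict minimum. Figures were drawn with matplotlib 3.10.9.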

Results

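The 6 arrays compared root transcripts of lecrk-I.9-1 seedlings with those of the wild type, 3 independent flasks of each, to ask which transcripts depend on LecRK-I.9, a plasma membrane kinase with an extracellular lectin domain that is known as a receptor for extracellular ATP. Between 69.8% and 77.7% of non-control spots were well above background per array. The 75th percentile of signal lay between 658 and 1301 intensity units.

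LecRK-I.9 (AT5G60300; TAIR10 chromosome 5, 24264862 to 24267973) was lower in lecrk-I.9-1 in all 3 mutant arrays. Its log2 signal was -3.87, -3.78 and -4.82 in wild type replicates 1 to 3 and -5.0, -5.93 and -5.54 in lecrk-I.9-1 replicates 1 to 3. The means were -4.16 ± 0.58 (SD, n = 3) and -5.49 ± 0.47 (SD, n = 3), a 2.52-fold lower level and a log2 difference of -1.33 with a standard error of 0.37. The difference did not pass the threshold in limma (adjusted p = 0.987), and an exact two-sided permutation test of this gene gave p = 0.1, the smallest that 3 against 3 allows. With scan as a block the log2 difference was -1.59, and it was -1.87 within scan 1 and -1.22 within scan 2. With normexp background correction it was -0.28. That setting adds an offset of 50 to each signal. The probe's mean signal was only 63.9 intensity units in the wild type and 18.4 in lecrk-I.9-1. The offset by itself therefore shrinks a difference at this level. The single probe was well above background on all 6 arrays. The files do not place it relative to the insertion, so it cannot tell a partial transcript from a full one. Signal from near-identical family members was not excluded either, so the fold and the signal left in lecrk-I.9-1 are those of the probe.

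Among the other lectin receptor kinases of clade I, LECRK-I.10, the next locus on chromosome 5, was at -4.12 ± 0.34 in the wild type and -3.35 ± 0.85 in lecrk-I.9-1 (SD, n = 3 each; limma adjusted p = 0.987). Of the 10 clade I genes tested, LecRK-I.9 included, 3 were higher and 7 lower, with a median log2 difference of -0.12, which was 0.03 with normexp background correction, 0.08 with scan as a block and 0.04 without wild type replicate 3. Camera did not call the list (adjusted p = 0.396), and LecRK-I.9 was its only member with all mutant arrays below all wild-type arrays. In the stretch of chromosome 5 around the insertion, from AT5G60200 to AT5G60400, 0 of 17 tested genes passed the threshold in limma, and LecRK-I.9 was the only one with an unadjusted p under 0.05 (1 of 17, 5.88%, against 2.90% of all genes; Fisher's exact test p = 0.393).

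The 10 genes of smallest p included 2 that were higher in lecrk-I.9-1 and 8 that were lower, and their groups did not overlap. AT5G35935, annotated as a transposable element gene, was 11.3-fold higher (log2 difference 3.5, SE 0.27, limma adjusted p = 0.366). AT5G26270, which encodes a protein of unknown function (chromosome 5, 9206508 to 9207512), was 8.09-fold higher (log2 difference 3.02, SE 0.26, adjusted p = 0.375). CCA1, a transcription factor of the morning loop of the clock, was 3.93-fold lower (log2 difference -1.98, SE 0.26), and AT2G46670, which encodes a CCT motif protein, was 5.47-fold lower. AT3G12320, of unknown function in the annotation, was 4.65-fold lower, and the B-box zinc finger gene BBX28 was 4.13-fold lower. CCD7, which encodes a carotenoid cleavage dioxygenase of strigolactone synthesis, was at least 1.41-fold lower and not well above background in any mutant array. In lecrk-I.9-1 replicate 1 the lowest signal well above background was -6.96, above CCD7 in wild type replicates 1 and 3 (-6.98 and -7.00). A wild-type level could thus have gone undetected on that array. With normexp background correction the log2 difference of CCD7 was 0.18, of the opposite sign. The subtilase gene AT4G21650 had a log2 difference of -2.04 and was well above background on 1 of the 3 mutant arrays. The zinc finger gene AT1G68360 and the RCC1 family gene AT3G53830 had log2 differences of -1.19 and -0.99. With scan as a block each of the 10 kept its sign, from -2.51 for AT2G46670 to 3.79 for AT5G35935.

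**Figure D1:**
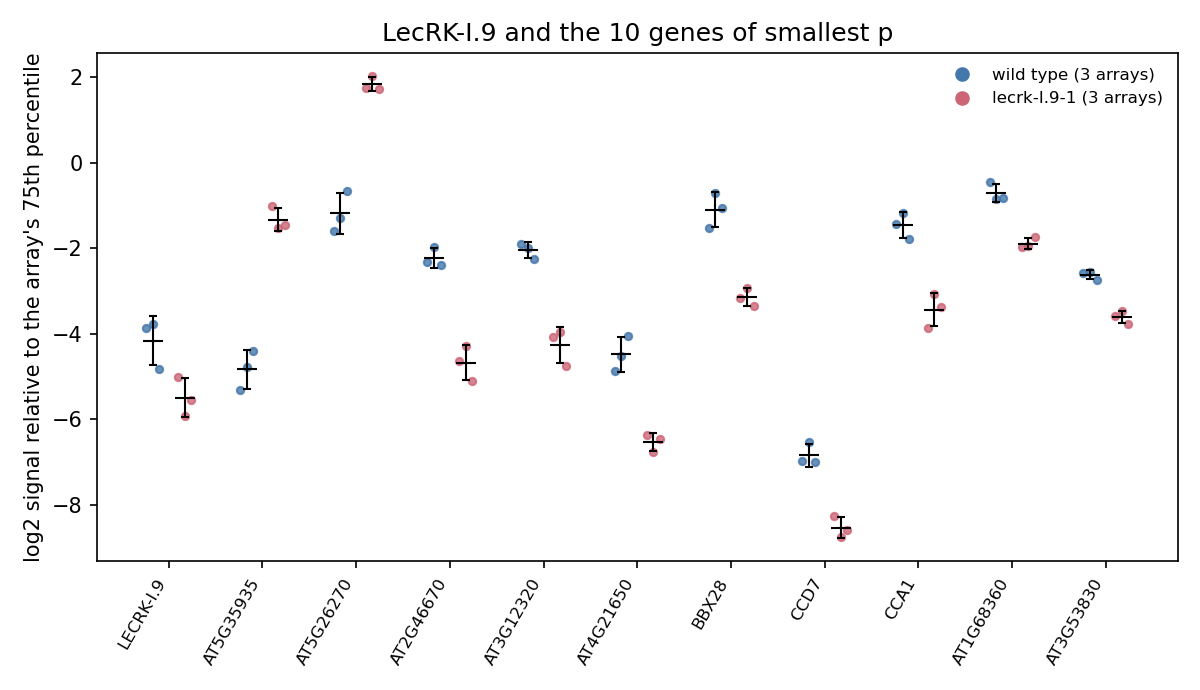
Log2 signal relative to each array's 75th percentile for LecRK-I.9 and the 10 genes of smallest p; points are arrays, bars are the mean ± SD of 3 arrays. In each of these genes the groups do not overlap, with AT5G35935 and AT5G26270 higher in lecrk-I.9-1 and the others lower; CCD7 was not well above background in any mutant array and AT4G21650 in only 1.

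None of these differences passed the threshold. In limma, 0 of 22468 genes had an adjusted p below 0.05, so 0 genes were both past this threshold and at least 2-fold apart. The smallest adjusted p was 0.366. It depended on the setting: in limma it was 0.058 without lecrk-I.9-1 replicate 1 and 0.065 in the authors' value table. With no filter it was 0.754, and without lecrk-I.9-1 replicate 3 it was 0.963. Without regard to the test, 726 genes were at least 2-fold apart. At an unadjusted p under 0.05 there were 651 genes, 491 lower and 160 higher in lecrk-I.9-1, where 1123 would come from chance alone. The groups did not overlap in 1580 genes (7.03%), against 10% by chance. The count of genes past the threshold was 0 in every other setting tried. The number at an unadjusted p under 0.05 was 1016 with scan as a block, 3526 with array weights, 999 without wild type replicate 1, 269 without wild type replicate 2, and 1921, 1476 and 394 without lecrk-I.9-1 replicates 1, 2 and 3.

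Genes of the cytokinin response were lower in lecrk-I.9-1. All 13 tested members had a negative log2 difference, with a median of -0.64, and 5 were lower in all 3 mutant arrays than in any wild-type array. The mean of the list was -0.94 ± 0.20 in the wild type and -1.63 ± 0.08 in lecrk-I.9-1 (SD, n = 3 arrays each). The type-A response regulators ARR6 and ARR7, which are induced by cytokinin and dampen its signalling, had log2 differences of -0.92 (SE 0.18) and -1.01 (SE 0.29). Over all genes 0 members passed in limma. Adjusted over the list alone, 1 passed, ARR6 (adjusted p = 0.034). The list fell in camera (adjusted p = 1.16e-08), but with an estimated correlation its adjusted p was 0.225. The difference of list means was -0.69 within scan 1 and -0.87 within scan 2, and the median was -0.70 with scan as a block (camera adjusted p = 1.78e-09; adjusted p = 0.677 with an estimated correlation). With normexp background correction the median was -0.41.

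Root hair genes were higher. Of 30 tested members, 29 had a positive log2 difference, with a median of 0.40. However, 0 were higher in all 3 mutant arrays than in any wild-type array. The mean of the list was -1.66 ± 0.36 in the wild type and -1.26 ± 0.40 in lecrk-I.9-1 (SD, n = 3 arrays each). Wild type replicate 3 (-1.27) lay above lecrk-I.9-1 replicates 1 and 2 (-1.61 and -1.33). EXT10, a cell wall extensin, was 1.48-fold higher (log2 difference 0.57, SE 0.24) and LRX2, a leucine-rich repeat extensin, 1.61-fold higher (log2 difference 0.69, SE 0.29). Neither separated the groups fully, and 0 members passed in limma, over all genes or adjusted over the list alone. The list rose in camera (adjusted p = 1.83e-06; adjusted p = 0.705 with an estimated correlation). The list means differed by 0.63 within scan 1 and 0.39 within scan 2, and the median was 0.42 with scan as a block (camera adjusted p = 1.78e-09; adjusted p = 0.900 with an estimated correlation). It was 0.15 without lecrk-I.9-1 replicate 3, 0.21 without wild type replicate 2, 0.60 without lecrk-I.9-1 replicate 1 and 0.71 with array weights. The list was also higher in the arrays of scan 1, of which 2 are lecrk-I.9-1, than in the other 3 (median 0.46; camera adjusted p = 6.86e-04; adjusted p = 0.815 with an estimated correlation). The epidermal cell fate regulators, a separate list, had 7 of 8 tested members higher and a median of 0.25, short of the threshold (camera adjusted p = 0.069), though called without lecrk-I.9-1 replicate 2 (adjusted p = 0.021; adjusted p = 0.625 with an estimated correlation). MYB23, a regulator of hair patterning, was at 0.55 and the receptor kinase SCM at -0.37.

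All 24 genes of the rapid elicitor, touch and calcium response had a negative log2 difference, with a median of -0.27 (camera adjusted p = 5.68e-04; adjusted p = 0.760 with an estimated correlation). NHL10 and WRKY53, both quickly induced by microbial elicitors, were at -0.87 and -1.18. Within scan 1 the list means differed by -0.80, but within scan 2 by 0.56, and the call was lost with scan as a block (median -0.08, adjusted p = 0.063) and without lecrk-I.9-1 replicate 2 (median -0.01, adjusted p = 0.244). The median was -0.80 without lecrk-I.9-1 replicate 1 and -0.13 without replicate 3. The list was lower in the arrays of scan 1, of which 2 are lecrk-I.9-1, than in the other 3 (median -0.77; camera adjusted p = 6.86e-04; adjusted p = 0.815 with an estimated correlation). Camalexin and indole glucosinolate genes were lower in 11 of 15 cases, with a median of -0.41 (camera adjusted p = 6.93e-03; adjusted p = 0.757 with an estimated correlation). MYB34, which activates indole glucosinolate synthesis, was at -1.05, and CYP79B3, an enzyme at its entry, was at -0.78. This call was lost with scan as a block, where the median was 0.05 (adjusted p = 0.784), without wild type replicate 3 (median -0.02, adjusted p = 0.697) and without lecrk-I.9-1 replicate 2 (median -0.18, adjusted p = 0.333). The list means differed by -0.10 within scan 1 and 0.13 within scan 2. This list too was lower in scan 1 than in the other arrays (median -0.62; camera adjusted p = 0.023; adjusted p = 0.815 with an estimated correlation).

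Genes of the response to abscisic acid and osmotic stress were lower in 14 of 19 cases (median -0.15; camera adjusted p = 0.020; adjusted p = 0.705 with an estimated correlation). RD22 and KIN2, both induced by drought or cold, had log2 differences of -1.40 (SE 0.34) and -1.38 (SE 0.36). The list means differed by -0.38 within scan 1 and -0.55 within scan 2, and the median with scan as a block was -0.32 (adjusted p = 2.82e-04; adjusted p = 0.900 with an estimated correlation). The call was lost without wild type replicate 1 (adjusted p = 0.119), without wild type replicate 2 (median -0.10, adjusted p = 0.120) and without lecrk-I.9-1 replicate 1 (median 0.04, adjusted p = 0.296), and the median was -0.28 without wild type replicate 3. Heat shock proteins were lower in 9 of 10 cases (median -0.26; camera adjusted p = 9.69e-03; adjusted p = 0.705 with an estimated correlation), with the small heat shock protein gene HSP18.2 at -1.13 and HSP70 at -0.33. Their means differed by -0.53 and -1.08 within scans 1 and 2, the median with scan as a block was -0.57 (adjusted p = 1.09e-05; adjusted p = 0.900 with an estimated correlation), and it was -0.62 without wild type replicate 3 and -0.08 with normexp background correction. Their call was lost without wild type replicate 1 (adjusted p = 0.180) or lecrk-I.9-1 replicate 1 (adjusted p = 0.324) and with array weights (adjusted p = 0.341). Genes of ethylene synthesis and response were lower in 15 of 16 cases (median -0.17; camera adjusted p = 0.046; adjusted p = 0.705 with an estimated correlation), with ACS7 and ACO4, which encode enzymes of ethylene synthesis, at -0.48 and -0.28. This call was lost with scan as a block (median -0.08, adjusted p = 0.307) and without any of 4 arrays, wild type replicate 3 and each lecrk-I.9-1 replicate (adjusted p up to 0.327). The median was -0.11 without wild type replicate 3 and -0.10 without wild type replicate 2, and within scans 1 and 2 the means differed by -0.04 and -0.15.

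Among the called lists, the spread between flasks of 1 genotype was largest for photosynthesis and core hypoxia (wild-type SD of list means 1.87 and 1.41). It was not confined to them. In lecrk-I.9-1 the SD was 0.73 for the rapid elicitor list and 0.57 for heat shock proteins, against genotype differences of -0.39 and -0.57. The photosynthesis list, a marker of shoot tissue, averaged 2.59, 0.94 and -1.14 in wild type replicates 1 to 3 and 1.59, -0.58 and -1.03 in lecrk-I.9-1 replicates 1 to 3. All 26 members had a negative log2 difference (median -0.70), with LHCB2.1 and LHCA4, both light-harvesting proteins, at -2.13 (SE 1.38) and -0.87 (SE 0.60). The list fell in camera (adjusted p = 5.47e-03; adjusted p = 0.786 with an estimated correlation), but without wild type replicate 1 its median was 0.10 (adjusted p = 0.593), and the call was also lost without lecrk-I.9-1 replicate 2 (adjusted p = 0.140) or replicate 3 (adjusted p = 0.270). The means differed by -3.40 within scan 1 and by 0.64 within scan 2, and the median with scan as a block was -1.53 (adjusted p = 9.56e-10; adjusted p = 0.900 with an estimated correlation). It was -1.60 without wild type replicate 3, -1.39 without lecrk-I.9-1 replicate 1, and -0.45 and -0.31 without lecrk-I.9-1 replicates 2 and 3. The core hypoxia list averaged -0.89, 0.77 and 1.91 in the wild-type replicates and -0.73, 0.45 and 0.02 in the lecrk-I.9-1 replicates. All 17 members had a negative log2 difference (median -0.65), with SUS4, a sucrose synthase, at -1.03 (SE 0.77) and the transcription factor HRE2 at -0.91 (SE 0.68). This list fell in camera (adjusted p = 5.47e-03; adjusted p = 0.760 with an estimated correlation), but the call was lost without wild type replicate 3 (median 0.03, adjusted p = 0.827), without lecrk-I.9-1 replicate 1 (median -0.36, adjusted p = 0.350) and with scan as a block (median -0.03, adjusted p = 0.823). Without wild type replicate 1 the median was -1.49. Its means differed by 1.13 within scan 1 and -1.51 within scan 2.

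Cell division genes, a marker of root tip tissue, were higher in 13 of 15 cases with a median of 0.11 (camera adjusted p = 0.042; adjusted p = 0.760 with an estimated correlation), and the stem cell regulator PLT1 and the cyclin CYCB1;2 were at 0.26 and 0.19. The call was lost with scan as a block (median 0.09, adjusted p = 0.249), and without lecrk-I.9-1 replicate 3 (median -0.0048, adjusted p = 0.810), and in 8 other settings, and the median was 0.25 without lecrk-I.9-1 replicate 2. The means differed by 0.12 within scan 1 and 0.10 within scan 2. All 4 root cap markers had a positive log2 difference (median 0.46; camera adjusted p = 0.058), with SMB at 0.25 and BRN2 at 0.64. They were not called as analysed, but were in 7 other settings, among them without wild type replicate 1 (median 0.84, adjusted p = 1.16e-03; adjusted p = 0.725 with an estimated correlation). Without wild type replicate 2 the median was 0.11 (adjusted p = 0.393).

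**Figure D2:**
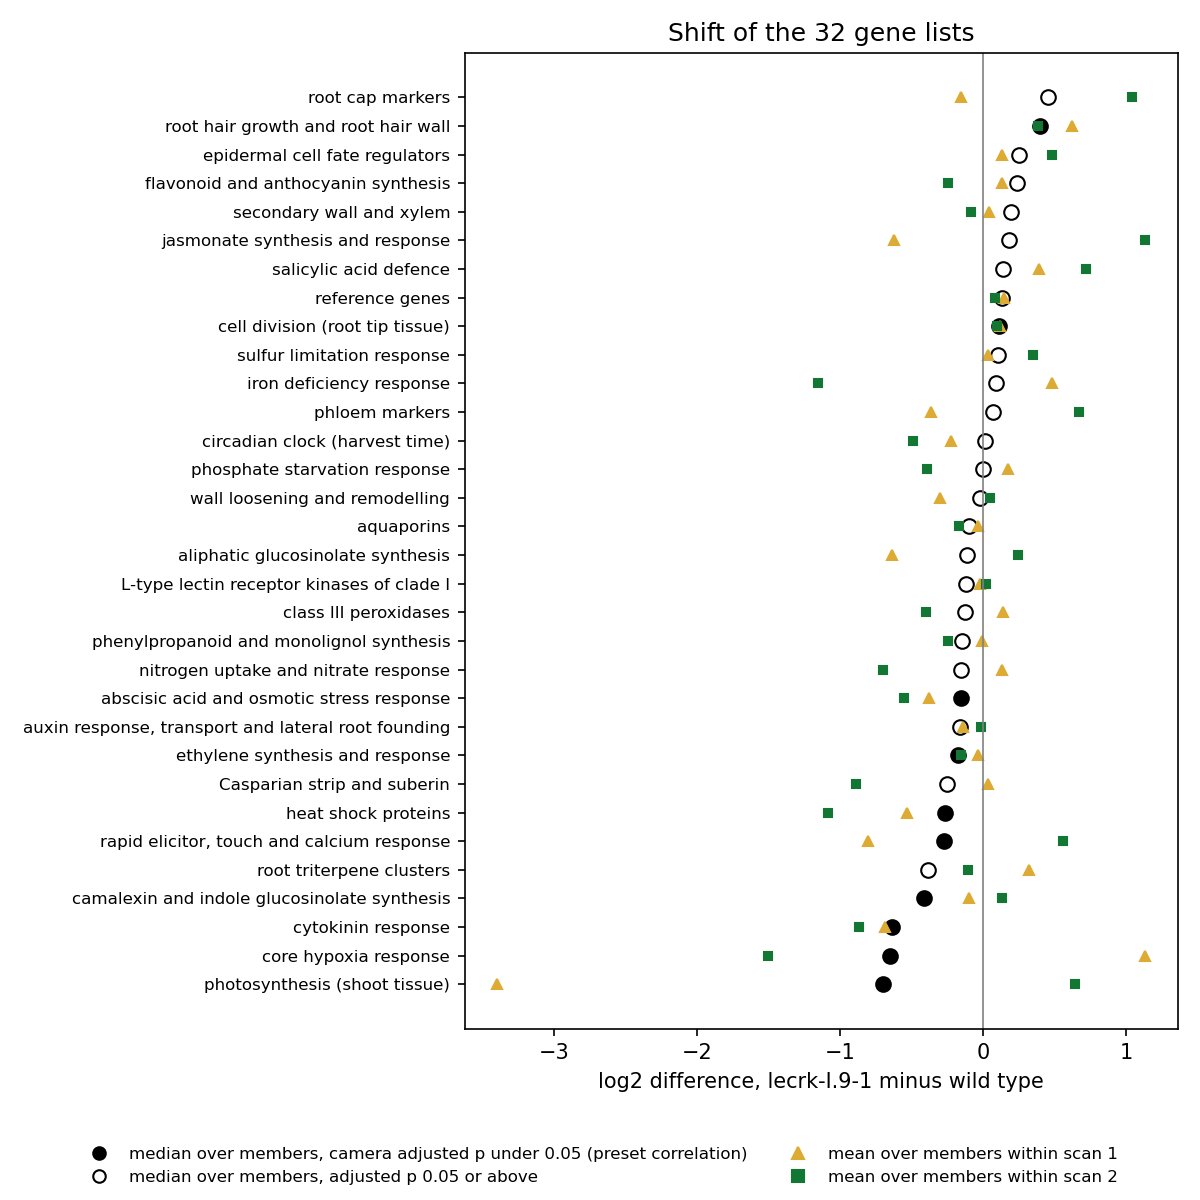
Log2 difference (lecrk-I.9-1 minus wild type) of the 32 gene lists: circles are medians over members, filled where camera with its preset correlation gave an adjusted p below 0.05, and triangles and squares are differences of list means within scans 1 and 2. Of the 10 filled lists, 8 are below 0 and 2 above; photosynthesis genes lie at -3.40 within scan 1 and 0.64 within scan 2, while cytokinin response genes lie below 0 in both.

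Circadian clock genes differed in both directions. The list holds genes that peak at different times of day, and its median of 0.01, mean of -0.33 and camera direction (lower, adjusted p = 0.120) differed in sign. Without lecrk-I.9-1 replicate 2, and in 3 other settings, camera called it lower (adjusted p = 0.048 without that array; adjusted p = 0.625 with an estimated correlation). Over all genes 0 of 19 passed in limma, but adjusted over the list alone 2 were higher and 7 lower, and 8 were lower and 3 higher in all 3 mutant arrays than in any wild-type array. CCA1 averaged -1.46 ± 0.30 in the wild type and -3.43 ± 0.39 in lecrk-I.9-1 (SD, n = 3 each; limma adjusted p = 0.005 adjusted over the list alone), with log2 differences of -1.79 within scan 1 and -2.68 within scan 2. ELF4, a member of the evening complex, averaged 1.15 ± 0.18 and 2.56 ± 0.35 (limma adjusted p = 0.005 adjusted over the list alone), with 1.42 and 1.19 within the 2 scans. Further members were chosen after their values were seen: the morning genes LHY, PRR9, RVE8, LNK1 and LNK2 had log2 differences of -1.46, -2.38 (well above background on 2 of the 3 mutant arrays), -1.08, -1.02 and -1.72, and the evening genes TOC1 and LUX 0.54 and 0.43. GI, which peaks late in the day, was at 0.01 and the morning gene RVE2 at 0.62. The sample titles carry the tag 0hr, whose reference point is not given, and no label gives the time of day of harvest.

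**Figure D3:**
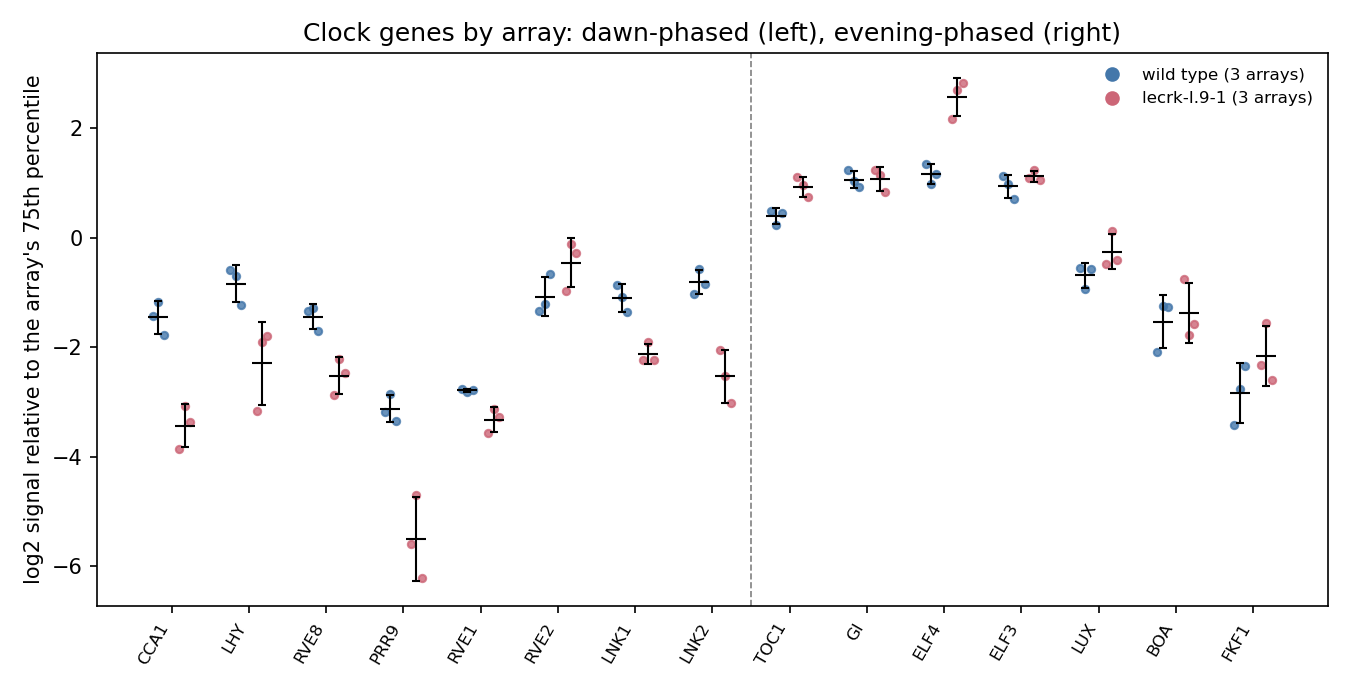
Log2 signal relative to each array's 75th percentile for 15 clock genes, 8 that peak around dawn and 7 towards evening, sorted by phase after the data were seen; points are arrays, bars are the mean ± SD of 3 arrays. In 7 of the 8 dawn genes (RVE2 is the exception) all lecrk-I.9-1 arrays lie below all wild-type arrays, and ELF4, TOC1 and LUX lie above them.

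Genes of jasmonate synthesis and response had a median of 0.18 but a mean of -0.03 (camera adjusted p = 0.396), and the lipoxygenase LOX2 and the storage protein VSP2 varied widely between flasks, at -1.99 (SE 0.92) and -2.29 (SE 1.1). LOX2 was well above background on 2 of the 3 mutant arrays. The jasmonate means differed by -0.62 within scan 1 and 1.13 within scan 2, and the median was -0.30 without lecrk-I.9-1 replicate 1 and 0.62 without replicate 2 (adjusted p = 2.21e-04 there; adjusted p = 0.625 with an estimated correlation). Salicylic acid defence genes had a median of 0.14 (adjusted p = 0.761), with PR5 at -0.94 and WRKY38 at 0.71. The median was -0.11 without wild type replicate 1 and -0.08 without lecrk-I.9-1 replicate 1. Aliphatic glucosinolate genes had a median of -0.11 (adjusted p = 0.228), which was 0.02 with scan as a block and 0.19 without lecrk-I.9-1 replicate 2. Without lecrk-I.9-1 replicate 1 it was -0.33 (adjusted p = 1.23e-03; adjusted p = 0.743 with an estimated correlation). In that list the mean of the transcription factor MYB29 was at least 3.52-fold lower (log2 difference -2.70, SE 0.79). It was not well above background in any mutant array, and its wild-type values were -4.50, -5.14 and -6.92. FMO_GS-OX1 was at -0.77. Auxin genes had a median of -0.16 (adjusted p = 0.120), or 0.01 with normexp background correction (adjusted p = 0.150), with IAA29 and LBD33 at -1.07 and -0.72, each well above background in 1 of the 3 mutant arrays and each of opposite sign with normexp background correction. The auxin list was called without wild type replicate 2 (adjusted p = 0.031; adjusted p = 0.725 with an estimated correlation).

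The 38 class III peroxidases had a median of -0.12 (camera adjusted p = 0.130), with AT5G06730 at -0.92 and AT1G14550 at -0.72. They were called without wild type replicate 2 (median -0.15, adjusted p = 0.027) and lecrk-I.9-1 replicate 2 (median -0.27, adjusted p = 3.05e-04), but with an estimated correlation the adjusted p was 0.725 and 0.625. Wall loosening genes had a median of -0.02 (adjusted p = 0.521), or 0.04 with scan as a block and 0.10 without lecrk-I.9-1 replicate 2, with XTH31 at -0.93 and the expansin EXPA1 at -1.10. Secondary wall and xylem genes had a positive log2 difference in 10 of 10 cases (median 0.20, adjusted p = 0.081), but the median was -0.03 with scan as a block and -0.05 without lecrk-I.9-1 replicate 3. The cellulose synthase CESA4 and the laccase LAC4 were at 0.35 and 0.28. Leaving out wild type replicate 1 or lecrk-I.9-1 replicate 1 gave a call (adjusted p = 1.99e-03 and 2.97e-03; adjusted p = 0.738 and 0.743 with an estimated correlation), and the list was higher in scan 1 than in the other arrays (median 0.57, camera adjusted p = 2.90e-06; adjusted p = 0.815 with an estimated correlation). Phloem markers had a median of 0.07 (adjusted p = 0.521), or -0.12 without wild type replicate 2 (adjusted p = 0.424), with PP2-A1 at 0.20 and APL at 0.08. Casparian strip and suberin genes had a median of -0.25 (adjusted p = 0.167), although CASP1 and ESB1, both of the Casparian strip, were at 0.42 and 0.49. The list was called without wild type replicate 2 (median -0.27, adjusted p = 0.045) and without lecrk-I.9-1 replicate 2 (median -0.58, adjusted p = 2.41e-04), but with an estimated correlation the adjusted p was 0.725 and 0.625. The Casparian median was -0.0030 without lecrk-I.9-1 replicate 1 and 0.01 with array weights. Phenylpropanoid and monolignol genes had a median of -0.15 (adjusted p = 0.120), with 4CL1 and CAD5 at -0.34 and -0.33. Without wild type replicate 3 the median was 0.0078, and without lecrk-I.9-1 replicate 2 the list was called (adjusted p = 0.014; adjusted p = 0.625 with an estimated correlation). Flavonoid genes had a median of 0.24 (adjusted p = 0.521), with MYB12 at 0.51. The mean of MYB11 was at least 2.23-fold lower, but its groups overlapped (SE of the log2 difference 0.66). With normexp background correction the log2 difference of MYB11 was 0.03. The flavonoid median was 0.07 without lecrk-I.9-1 replicate 3, 0.42 without wild type replicate 2, -0.02 with array weights and -0.05 with wild type replicates 1 and 3 left out. Root triterpene clusters had a median of -0.38 (adjusted p = 0.332), with PEN1 at 0.33 and THAS1 at -0.96. The median was 0.21 with scan as a block and 0.10 without wild type replicate 3. Without wild type replicate 1 it was -0.81 (adjusted p = 0.017; adjusted p = 0.738 with an estimated correlation). Aquaporins had a median of -0.09 (adjusted p = 0.327), with PIP2;1 and PIP2;5 at -0.51 and -0.75. Their median was 0.02 without wild type replicate 2.

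Iron deficiency genes had a median of 0.09 (camera adjusted p = 0.227), with CYP82C4 at 0.36 and BHLH100 at 0.64, and their means differed by 0.48 within scan 1 but -1.15 within scan 2. The iron median was -0.19 with scan as a block, -0.04 without wild type replicate 3, and -0.12 and -0.02 without lecrk-I.9-1 replicates 2 and 3. Without replicate 1 it was 0.57 (adjusted p = 3.97e-07; adjusted p = 0.656 with an estimated correlation). Phosphate starvation genes had a median of -0.0005 and a camera direction towards higher (adjusted p = 0.816; median 0.02 with scan as a block), with SQD2 at 0.45 and G3PP1 at -0.67. Nitrogen genes had a median of -0.15 (adjusted p = 0.521), or 0.05 with normexp background correction (adjusted p = 0.118), with HRS1 at -0.59 and the nitrate reductase NIA2 at -0.39, and sulfur limitation genes a median of 0.10 (adjusted p = 0.130), with LSU2 at 0.42 and ATSDI1 at 0.85. Without lecrk-I.9-1 replicate 1 the nitrogen median was 0.14 (adjusted p = 0.047; adjusted p = 0.656 with an estimated correlation), and the sulfur median was -0.0068 with scan as a block. The reference genes had a median of 0.14 (adjusted p = 0.228), with the actins ACT2 and ACT8 both at 0.22.

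Some lists not called at the settings first chosen were called by camera under others, none of them with an estimated correlation. Quantile normalisation, normexp background correction and the authors' value table each called class III peroxidases (adjusted p = 0.015, 9.53e-04 and 0.014), phenylpropanoid genes (0.015, 3.25e-03 and 0.018) and aquaporins (8.77e-03, 0.031 and 8.62e-03) lower, with an adjusted p of at least 0.510 with an estimated correlation. Normexp correction and the authors' table called Casparian strip and suberin genes lower (adjusted p = 0.031 and 0.049; adjusted p = 0.644 and 0.728 with an estimated correlation), and normexp correction called triterpene clusters lower (adjusted p = 0.048, and 0.578 with an estimated correlation). Quantile normalisation and the authors' table called epidermal cell fate regulators higher (adjusted p = 0.027 and 0.017; adjusted p = 0.549 and 0.564 with an estimated correlation). With the mean over probes, auxin genes were called lower (adjusted p = 0.049; adjusted p = 0.699 with an estimated correlation). Array weights called iron deficiency (adjusted p = 0.033), sulfur limitation (0.045) and xylem genes (2.22e-03) higher and aliphatic glucosinolate genes (0.030) lower, each with an adjusted p of 0.721 with an estimated correlation. The phloem markers were called higher with wild type replicates 1 and 3 left out (adjusted p = 0.011; adjusted p = 0.687 with an estimated correlation).

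Leaving out 1 array moved the medians of the lists not called. The range was -0.29 to -0.05 for class III peroxidases, -0.21 to 0.10 for wall loosening genes, -0.12 to 0.26 for phloem markers, -0.22 to 0.0078 for phenylpropanoid genes, -0.15 to -0.07 for auxin genes, 0.12 to 0.35 for epidermal cell fate regulators and -0.09 to 0.02 for aquaporins. It was -0.11 to 0.34 for salicylic acid defence, -0.12 to 0.11 for phosphate starvation, 0.03 to 0.23 for sulfur limitation, -0.28 to 0.04 for clade I lectin receptor kinases, -0.12 to 0.14 for clock genes and 0.03 to 0.12 for reference genes. Between scan 1 and the other arrays, camera also called Casparian strip and suberin (median 0.38), iron deficiency (0.69) and nitrogen genes (0.42) higher in scan 1, and aliphatic glucosinolate (-0.35) and triterpene genes (-0.86) lower (adjusted p up to 0.042; adjusted p = 0.815 with an estimated correlation).

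The arrays did not group by genotype. The first principal component, with 44.4% of the variance, separated the 3 arrays of scan 1 from the other 3. The median correlation of 2 arrays across genes was 0.966 within a genotype and 0.971 between genotypes.

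**Figure D4:**
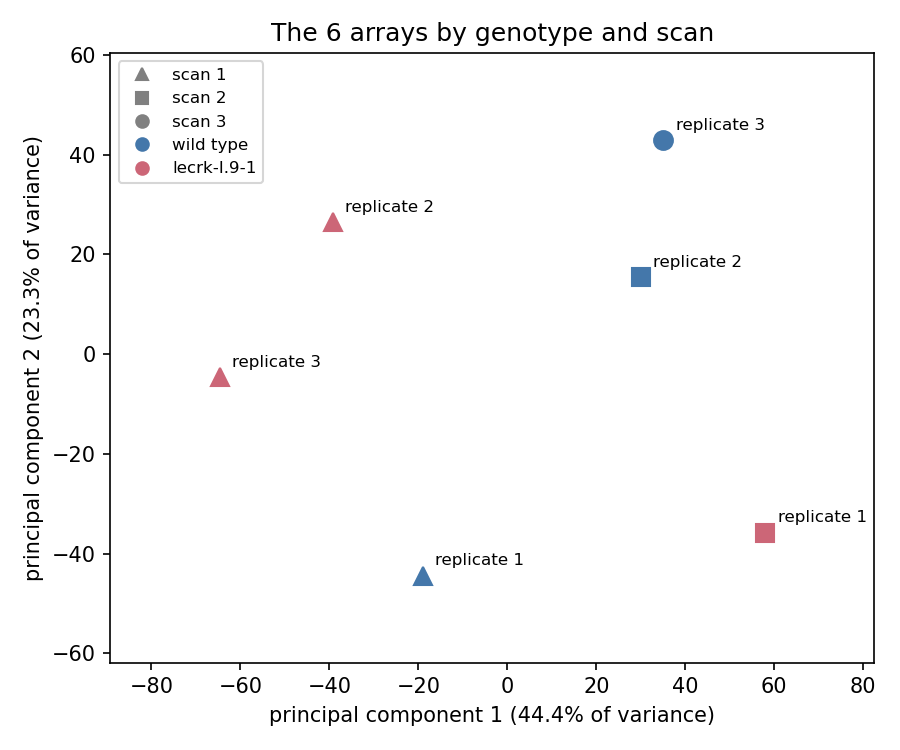
The 6 arrays on the first 2 principal components of the tested genes (44.4% and 23.3% of the variance), by genotype (colour) and scan (symbol). Wild type replicate 1 lies with lecrk-I.9-1 replicates 2 and 3, the other arrays of its scan, at negative values of the first component.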

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

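The count of genes past the threshold, the count both past it and at least 2-fold apart, the count near the insertion and the number of lists called with an estimated correlation were 0 in all 17 other settings, including the 1 added after the data were seen (wild type replicates 1 and 3 left out). LecRK-I.9 was lower in all 17, with an adjusted p between 0.313 and 1.000. The number of genes at an unadjusted p under 0.05 was 651 and moved to 1090 with no filter on dim probes, 1016 with scan as a block and 3526 with array weights. It ranged from 269 (without wild type replicate 2) to 1921 (without lecrk-I.9-1 replicate 1) with 1 array left out, and was 394 without lecrk-I.9-1 replicate 3, 999 without wild type replicate 1 and 1476 without lecrk-I.9-1 replicate 2. The number of lists called by camera was 10 and moved to 16 with quantile normalisation, 16 in the authors' value table and 5 with scan as a block, and ranged from 6 (without wild type replicate 3) to 12 with 1 array left out. Fry tests, chosen after the data were seen, called 2 lists in either direction (cytokinin response and clock) and 0 on balance one way. In splits of the arrays that mix the genotypes, fry called up to 9 lists in either direction. The cause of the differences between settings was not tested. Leaving out the filter adds dim genes to the test, and the scan block leaves wild type replicate 3, alone in its scan, without weight.

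The cytokinin and root hair lists were called in the same direction in all 17 settings at the preset correlation, and in 0 with an estimated correlation (smallest adjusted p = 0.164 and 0.510). The photosynthesis list reversed to a median of 0.10 without wild type replicate 1; with 1 array left out its median ranged from -1.60 to 0.10. The nitrogen list, not called with all arrays, was called higher without lecrk-I.9-1 replicate 1 (median 0.14; adjusted p = 0.047, and 0.656 with an estimated correlation), and with 1 array left out its median ranged from -0.14 to 0.14. Of the lists, 16 kept their camera direction in all settings and 16, with photosynthesis as the only one of the 10 lists called at the settings first chosen, changed it in at least 1. Outside those 10, 16 lists were called in at least 1 other setting, 0 of them with an estimated correlation. A change of direction where neither setting called a list or gene was counted as a move, not a reversal (41 list values and 25 gene values). Among genes named by the rule, 67 kept their sign and 6 did not: CCD7, MYB11, IAA29 and LBD33 with normexp, APL without wild type replicate 2 and ACO4 without wild type replicates 1 and 3. Dim probes limit what could be measured in the first 4, which were not well above background on all mutant arrays. The normexp offset of 50 weighs most on such dim probes, so their sign under that setting is not taken to tell a direction.

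Same-numbered arrays did not deviate together (correlations of deviations from the group means -0.21, 0.03 and -0.15 for replicates 1 to 3), so the numbers were not taken to pair the samples. With the replicate block 0 genes passed the threshold, 769 had an unadjusted p under 0.05 and 12 lists were called by camera.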

Other observations

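The tests below were chosen after the result they measure had been seen, except those of dim signal and of normalisation for scan 1 and of neighbouring genes for AT5G35935 and AT5G26270; genes and sets named here for the first time were also chosen after their values were seen.

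Further members of the cytokinin list were lower too. The response regulators ARR5 and ARR4 had log2 differences of -0.96 and -0.42, and the cytokinin oxidase gene CKX3, whose product breaks cytokinin down, -0.81, each with all mutant arrays below all wild-type arrays. ARR3 was at -0.06. A set of genes outside clade I annotated as lectin protein kinases or lectin receptor kinases was defined after 3 of its members had been noticed. The annotation wording does not restrict it to 1 type of lectin domain. With these 3 members included, 38 of 48 genes were lower, with a median of -0.21 (camera p = 2.71e-07, and p = 0.118 with an estimated correlation). AT5G01550 was at -1.40, AT4G02410 at -0.72 and AT4G28350 at -1.09. Among subtilase genes, AT4G21630, near AT4G21650 on chromosome 4, was at least 3.21-fold lower, being well above background in 0 of 3 mutant arrays. JMJD5, a demethylase-family gene linked to the clock, was 3.1-fold higher, and the transposable element gene AT5G33395 at least 3.66-fold higher, being above background in 0 of 3 wild-type arrays. None of these genes passed in limma (adjusted p between 0.812 and 0.993).

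In 7 of 8 clock genes that peak around dawn all lecrk-I.9-1 arrays lay below all wild-type arrays (RVE2 was at 0.62), and in 3 of 7 evening genes they lay above (GI was at 0.01). The mean of 8 dawn genes minus that of 7 evening genes, phases assigned from general knowledge to 15 of the 19 list members, was -1.36 ± 0.19 in the wild type and -3.04 ± 0.25 in lecrk-I.9-1 (SD, n = 3; exact permutation test p = 0.1, the smallest possible). A difference between scans is argued against by -1.61 and -2.12 within scans 1 and 2 and -1.83 ± 0.19 (SE) with scan as a block. Shoot tissue in some flasks, the candidate first tested by leaving out wild type replicate 1 (-1.65) and then, in place of that, by the photosynthesis mean as a covariate, is argued against by a difference of -1.69 ± 0.22 (SE) with that covariate. Harvest of the genotypes at different times of day could give the same values, with evening genes higher by 0.49 on average. It cannot be told apart from an effect of the genotype, since no label gives a time of day. The same limit holds for any other transcript that varies over the day, and which of the genes and lists above do so was not tested.

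AT5G35935 and AT5G26270, 11.3-fold and 8.09-fold higher in lecrk-I.9-1, had the smallest p of all genes tested. A difference between scans is argued against by a lowest within-scan difference of 3.03. For AT5G35935, which unlike AT5G26270 is annotated as a transposable element gene, a rise of that whole class is argued against by its median of -0.21 (SD 0.63, 220 genes). That median does not cover a rise confined to some elements. More copies of the stretch around each gene would raise its neighbours, but the medians of the 10 nearest tested loci were -0.12 and -0.16; nearness was taken from the order of locus codes, since the files give no usable position for AT5G35935. A change at or near each gene in this line, linked or not linked to the insertion, may account for them and was not tested, since no sequence of the line and no other allele was measured.

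The arrays of scan 1 stood apart from the other 3, with 450 genes called in limma between these sets (32 higher, 418 lower in scan 1), against 0 between the genotypes. Of the called genes, 69.3% lay in the dimmest 25% of tested genes, which goes with signal near background. Under quantile normalisation 183 genes were called. Quantile normalisation evens out any difference in distribution between arrays, whatever its source. The lower count therefore cannot tell whether the shift by the 75th percentile was part of the cause. Hybridisation and scan in one session could also give the 450 genes and cannot be told apart from a difference between the flasks, since each flask was scanned once.

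The 6 arrays can be split into 2 sets of 3 in 10 ways, too few for a share under 0.05. With 0 genes called between the genotypes, 10 of 10 splits give as many whatever the data, so that count tests nothing; the highest count in another split, 450, came from scan 1 against the rest and points to a structure of the samples. As many lists (10) were called by camera in 7 of 10 splits, and at most 13 in another. By fry in either direction, 2 lists were called between the genotypes, 2 in another split and 9 between scan 1 and the rest. For the cytokinin list, a camera p as small as the real one (3.61e-10) came in 1 of 10 splits, the real one, and the smallest p of another was 1.96e-04. For the clock list tested in either direction by fry, a p as small as the real one (9.49e-05) came in 1 of 10 splits, the real one, and the smallest other was 0.434. Each list had the smallest p of the 32 lists in its test between the genotypes, a choice that favours the real split. The smallest p over all lists was not compared between splits, so no conclusion is drawn from these shares.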
